A study of Homo sapiens with 6 samples.

How the data were processed

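Gene expression was measured in 6 samples of the 201B7 human induced pluripotent stem cell line at day 3 of ocular differentiation, each on another substrate, with 1 one-colour array per sample. Per the labels' protocols, total RNA was prepared with a column kit and turned into Cy3-labelled cRNA with an Agilent low-input amplification kit. Per the file headers, spot intensity was read with Agilent Feature Extraction 11.5.1.1 and its one-colour gene expression protocol, which subtracted background and detrended each array but did not normalize between arrays. The intensity used as the main value is the processed signal of each spot, as deposited, on a linear scale. The deposited value table held the same processed intensity multiplied by 1 constant per array (3.94 for LN111E8, 3.79 for LN211E8, 4.45 for LN332E8, 4.28 for LN411E8, 4.07 for LN511E8 and 3.70 for VN). Its values are therefore linear and not centred by gene, and what set the constants is not given in the sources used here. Its column medians were 100.4 for LN111E8, 100.1 for LN211E8, 79.2 for LN332E8, 98.2 for LN411E8, 106 for LN511E8 and 93.7 for VN.

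Each array held 60901 non-control spots of 58201 probes. Spots marked as outliers by the scanner software (45 to 87 per array) were left out, and spots of the same probe were averaged on the log2 scale. Each array was scaled by subtracting the log2 of its 75th percentile of processed signal, which lay at 207 for LN332E8 and 225 to 252 for the other 5. The files name probes by accession and not by symbol. Accessions were matched without versions to a RefSeq gene table of assembly GRCh38.p14. Of the probes, 31104 matched a single gene and 27097 matched no gene or more than 1, and 22374 genes had at least 1 probe. The file headers annotate the array design on the build hg19, so no coordinates are given. Where a gene had several probes (6735 genes), the probe above background on most arrays, then the brightest, stood for the gene, and the signs of the others were checked. Genes above background on at least 1 array numbered 17655, and 14670 were so on all 6. Genes of the sex chromosomes that can report on a person were left out of all tables.

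Every laminin was compared with VN, and LN211E8, LN332E8 and LN511E8 with one another, which makes 8 pairs. A gene entered a pair when its signal was well above background, by the scanner software's own flag, on at least 1 of its arrays. It counted as above background on an array if any of its probes was. Where the dimmer side was not well above background, its value was set to the higher of its own signal and the lowest signal above background on that array, and the difference is a bound, written "at least". With 1 array per substrate no test across genes was run, and genes were counted by a difference of at least 2-fold. Comparisons with VN share the VN array, so they were neither correlated nor overlapped. To describe distance, the SD of log2 differences was taken over genes for all 15 pairs of arrays.

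Before the data were examined, 35 gene lists were fixed (819 entries, 812 on the array), along with the rule for named genes. A gene could be in several lists, as LHX2 and PAX6 were in both Neuroectoderm and Eye field and retina. Each list's median difference was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression, and called outside the random range at or below the 2.5th or at or above the 97.5th percentile. Over the 8 pairs, 150 of 280 combinations lay outside, where 14 are expected for lists of unrelated genes. The genes named are, per pair, drawn from the 8 largest higher and the 8 largest lower differences among genes with a real symbol, detected on both arrays, whose brighter signal reached the median of detected probes. Per array, they are up to 5 with the largest gap to every other substrate, detected on all arrays. Per list outside the random range, they are up to 4 members with the largest difference in its direction. For the lists Pluripotency, Neuroectoderm, Eye field and retina, Surface and non-neural ectoderm, Neural crest, YAP/TEAD targets, Integrins, and Laminin chains and basement membrane, 2 to 4 members count under the rule whether or not the list left the range. Some genes that the rule takes are not reported here. Genes whose levels are given on all substrates were named by this rule in a pair, except POU5F1, SOX1, SOX2 and TP63, which were picked from the lists after their values were seen.

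The alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median of detected probes, scaling to spike-ins, the deposited value table, genes detected on both arrays only, no filter and no bound, the mean of all probes of a gene, the mean of a list, and random lists without matching. Normexp was planned on the mean spot signal, a column not used here, and ran on the median spot signal and the median local background. An added alternative, chosen after seeing the data, leaves out the LN332E8 array when genes above or below every other substrate are counted. The functions were tested on simulated data built on the VN array, with noise set from the closest pair of arrays. Over 15774 genes, they counted 96.0% of 50 genes set 1.5 log2 apart, all 50 at 2 and at 3 log2, none of 50 at 0.5 log2, and 1 of 15574 unchanged genes. Of 200 simulated lists with no change, 6.5% lay outside the random range, and of 100 lists of 20 genes moved by 0.5 log2 all did. The simulated noise, an SD of 0.18 log2, was the same at every signal level and independent between genes. These rates therefore check the functions and are no error rates of the real arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.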

Results

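The series holds 6 one-colour microarrays of human induced pluripotent stem cells of the 201B7 line, an established line, taken at day 3 of differentiation toward ocular cells. The cells had been placed on 6 coatings, with 1 array each. Of these, 5 were recombinant E8 fragments of laminins, the integrin-binding ends of basement membrane proteins, named LN111E8, LN211E8, LN332E8, LN411E8 and LN511E8 after their alpha, beta and gamma chains. The sixth was vitronectin (VN), an adhesive glycoprotein of plasma that is not a laminin and served here as the point of reference. The comparisons ask how gene expression early in ocular differentiation depended on the laminin isoform under the cells. There was 1 array per substrate and so no replicate: no difference below has a replicate check, and none carries a test or an error between cultures. Levels are log2 signals relative to the 75th percentile of the same array, and differences between substrates are differences of such levels.

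The share of probes well above background was 53.1% on LN111E8, 54.8% on LN211E8, 51.2% on LN332E8, 52.2% on LN411E8, 47.4% on LN511E8 and 46.5% on VN. No spot was saturated on any array. Repeated spots of the same probe had a median SD of 0.05 to 0.07 log2 within an array, and the number of arrays, not this technical spread, limits the precision. The LN332E8 array lay on a second slide, read on another day than the other 5, so slide and substrate cannot be told apart in any LN332E8 value. The LN511E8 and VN arrays shared a slide column, and their dimmest detectable signals lay higher, at 23.4 and 24.9 units against 11.3 to 13.5 on the other arrays. On the same slide, LN211E8 and VN shared a row, as did LN111E8 and LN511E8.

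Of the genes measured, 13 of 22 Neuroectoderm genes and 7 of 16 Eye field and retina genes were highest on LN511E8, and 3 of the latter each on LN211E8, LN332E8 and VN. Of 24 Neural crest genes, 10 were highest on VN and 7 on LN211E8, and of 24 Surface and non-neural ectoderm genes 7 and 12. On LN111E8 both groups were low: relative to each gene's mean over the 6 arrays, the median was -0.55 for Eye field and retina genes and -0.54 for Neural crest genes. RAX, a homeobox gene required for eye formation, had a level of -1.92 on VN, -0.31 on LN211E8, 0.91 on LN111E8, 2.72 on LN332E8, 3.56 on LN411E8 and 5.31 on LN511E8. LHX2, needed for the optic vesicle, lay between -2.0 and -1.6 on VN, LN211E8 and LN111E8, at 2.28 on LN332E8, at 3.60 on LN411E8 and at 4.93 on LN511E8. PAX6, a master gene of eye development, was at 0.46 on VN, 0.09 on LN111E8 and 3.96 on LN511E8. PAX3 and PAX7, paired-box genes of the neural plate border and neural crest, were at 3.17 and 2.91 on VN and 2.49 and 2.74 on LN211E8, against -1.16 and -1.9 on LN511E8. PAX3 lay at -0.92 on LN332E8, and by this probe it was not well above background on LN111E8 and LN411E8. GRHL3, a transcription factor of surface ectoderm, was at 3.54 on VN and 3.40 on LN211E8, and at 0.62 or below on the other 4 substrates. The pluripotency gene POU5F1 was among the brighter genes on every array, with levels of 8.32 to 8.96, and SOX2 lay at 6.88 to 7.42. SOX1, an early neural gene, and TP63, a gene of stratified epithelia, were not well above background on any array.

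**Figure D1:**
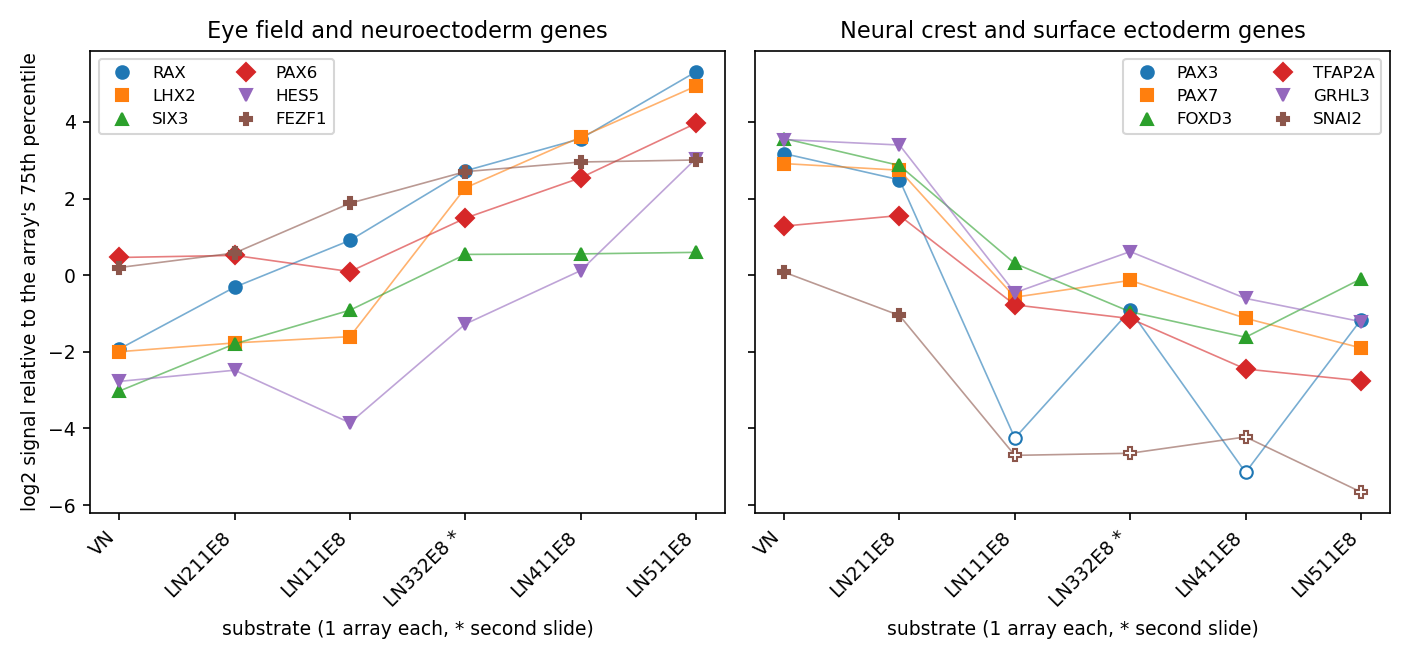
Log2 signal relative to the array's 75th percentile (vertical axis) on each of the 6 substrates (horizontal axis, 1 array each), with filled symbols for signals well above background, open symbols for signals that were not, and lines only to guide the eye. RAX lay at -1.92 on VN and 5.31 on LN511E8, whereas GRHL3 lay at 3.54 on VN and -1.21 on LN511E8.

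Over the 14670 genes well above background on all 6 arrays, LN211E8 and VN were the closest pair of arrays, with an SD of log2 differences of 0.26, and LN332E8 and VN were the farthest apart, at 0.69. LN411E8 lay at 0.35 from LN111E8, 0.35 from LN332E8 and 0.36 from LN511E8. The distance of LN511E8 from LN332E8 was 0.51. The distances that involve LN332E8 also hold the difference between the slides.

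**Figure D2:**
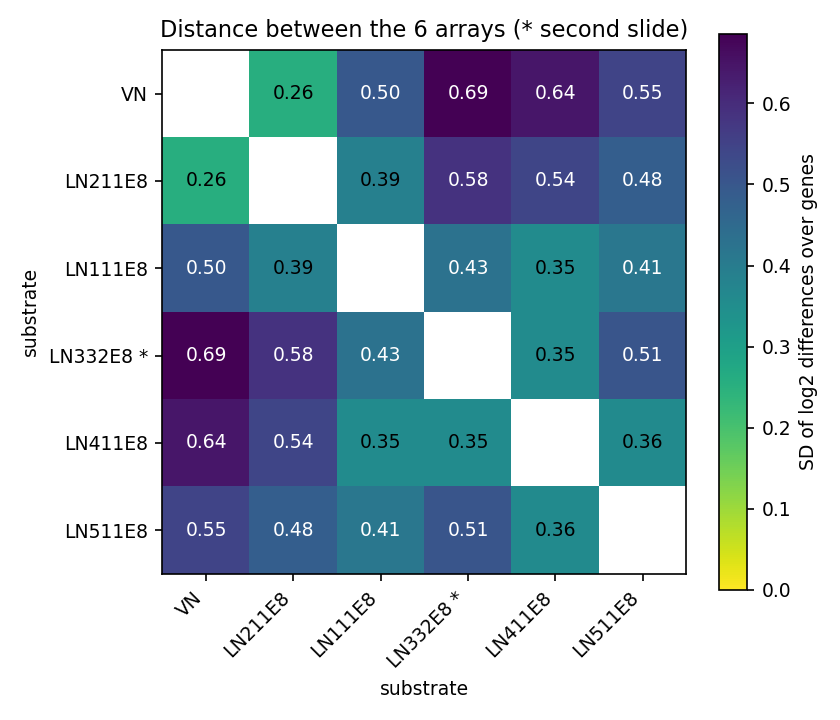
SD of the log2 differences over 14670 genes (colour and printed value) for each of the 15 pairs of arrays, with the substrates on both axes and an asterisk on LN332E8, the array of the second slide. LN211E8 and VN were the closest pair (0.26), and LN332E8 and VN the farthest apart (0.69).

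LN511E8 was compared with VN first. Among the genes with the largest higher values on LN511E8, RAX was 151-fold higher, LHX2 122-fold, the Notch target HES5 56.3-fold, the antisense transcript SIX3-AS1 40.9-fold, SIX3 12.3-fold and PAX6 11.3-fold. SMOC1, a secreted matrix protein, was 15.6-fold higher, and the antisense transcript FEZF1-AS1 12.1-fold. The largest lower value was that of HAPLN1, a hyaluronan-binding link protein, at 260-fold. Other large lower values were those of PAX7 (28.1-fold, or 1.27 log2 by its other probe), GRHL3 (26.9-fold), the neuropeptide gene NPY (26.6-fold), CABP7 (25.3-fold), PAX3 (20.2-fold) and CYP1B1 (17.7-fold).

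By gene list, the median difference from VN is given with the percentile it took among 10000 random lists of the same size and expression, which describes these arrays only, since genes of a list are co-regulated. Of 22 measured Neuroectoderm genes, 15 were at least 2-fold higher on LN511E8 and none lower (median 1.19, percentile 100), among them LMO3 at 11.2-fold. Of 16 Eye field and retina genes, 7 were at least 2-fold higher and 2 lower (median 0.71, percentile 100). LHX2 and PAX6 are in both of these lists, so their medians are not independent. Of 23 Neural crest genes, 14 were at least 2-fold lower and 1 higher (median -1.28, percentile 0), with TFAP2B at least 17.8-fold and TFAP2A 16.4-fold lower. Of 23 Surface and non-neural ectoderm genes, 16 were at least 2-fold lower and none higher (median -1.44, percentile 0), with WNT6 13.6-fold and GATA3 at least 7.98-fold lower. Preplacodal and lens genes were lower as well (median -0.84, 8 of 16 at least 2-fold lower), including DLX5 at 4.53-fold and DLX6 at 4.55-fold. The Epithelial adhesion list had a median of -0.54 (percentile 0), with the tight junction gene CLDN4 2.71-fold and E-cadherin (CDH1) 2.08-fold lower. NOTCH pathway genes had a median of 0.40 (percentile 99.98), led by HES5, MFNG at 6.69-fold and DLL3 at 2.48-fold.

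Signalling targets and matrix genes differed too. WNT targets had a median of -0.83 on LN511E8 against VN (percentile 0), with SP5 3.69-fold, RNF43 2.93-fold and AXIN2 2.84-fold lower, and BMP/SMAD targets a median of -0.60 (percentile 0), with BMP2 5.94-fold lower. Without the targets that are also in lineage or WNT lists, the BMP median was -0.27 (percentile 3.4), within the random range, and the mean -0.64, with 4 of 14 at least 2-fold lower and none higher. Pluripotency genes had a median of -0.46 (percentile 0), with FOXD3, which is also a neural crest gene, 12.7-fold and NODAL 2.74-fold lower, and 20 of 24 members within 2-fold. Laminin chain and basement membrane genes had a median of 0.21 (percentile 99.8), with nidogen NID1 2.64-fold higher. Neither Integrins (median -0.22, percentile 5.62) nor YAP/TEAD targets (median -0.16, percentile 17.9) left the range of random lists, although ITGA1 was 3.72-fold lower and GADD45A 3.13-fold lower. Of 16045 genes compared, 692 were at least 2-fold higher and 663 lower on LN511E8, against 279 and 308 with normexp background correction. The higher genes made up 51.1% of these, and 38.4% when arrays were scaled to their spike-ins.

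LN411E8 was compared with VN next. LHX2 was 48.5-fold higher, RAX 44.9-fold, SIX3-AS1 35.1-fold and SIX3 12.0-fold. TXNIP, a glucose-responsive regulator of thioredoxin, was 15.6-fold higher, and the imprinted non-coding RNA MEG3 10-fold. HAPLN1 was 150-fold lower, NPY 63.1-fold, the natriuretic peptide gene NPPB 46.1-fold, the fetal serum protein gene AFP 42.7-fold, FOXD3 36.4-fold, the BMP-binding protein gene BMPER 34.4-fold, NNMT 29.5-fold and TTC29 24.4-fold. EXD3 was 3.53 log2 higher by its chosen probe, whereas its other probe had the opposite sign.

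On LN411E8, 9 of 22 Neuroectoderm genes were at least 2-fold higher than on VN and 2 lower (median 0.73, percentile 100), with HES5 7.42-fold, FEZF1 6.74-fold and DLK1 4.23-fold higher. Eye field and retina genes split, with 6 of 15 at least 2-fold higher and 5 lower (median 0.38, percentile 99.4), and PAX6 4.23-fold higher. Of 23 Neural crest genes, 14 were at least 2-fold lower and none higher (median -1.49, percentile 0), with PAX3 at least 152-fold and MSX1 at least 24.4-fold lower. Surface and non-neural ectoderm genes had a median of -0.99 (percentile 0), with GRHL3 17.7-fold and TFAP2A 13.3-fold lower. WNT targets had a median of -1.04 (percentile 0) and Pluripotency genes of -0.38 (percentile 0.01), with NANOG 2.35-fold lower. Laminin chain and basement membrane genes had a median of 0.41 (percentile 99.98), with NID2 2.29-fold and HSPG2 1.93-fold higher. Integrins (median -0.21, percentile 5.45) and YAP/TEAD targets (median -0.23, percentile 3.33) stayed within the random range, and ITGA1 was 6.04-fold lower. Of 16662 genes compared, 820 were at least 2-fold higher and 1131 lower, against 395 and 481 with normexp. The higher genes made up 42.0%, and 25.8% with spike-in scaling.

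LN332E8 lay on the second slide, so its differences from VN may hold a slide difference that cannot be separated. RAX was 25.1-fold higher on LN332E8, SIX3-AS1 22.6-fold, LHX2 19.4-fold, TXNIP 13.4-fold, MEG3 13.1-fold and SIX3 11.8-fold. EXD3 was 14.6-fold higher by its chosen probe and 1.04 log2 lower by its other probe. HAPLN1 was 62.4-fold lower, AFP 33.2-fold, TTC29 28.3-fold, NPY 24.7-fold, FOXD3 23.0-fold, the hypoxia factor gene EPAS1 18.4-fold, CABP7 17.7-fold and PAX2, a gene of the optic stalk, 17.5-fold.

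On the same LN332E8 array, 15 of 23 Neural crest genes were at least 2-fold lower than on VN and none higher (median -1.48, percentile 0), with TFAP2B at least 31.1-fold, SNAI2 at least 19.4-fold and PAX3 17.1-fold lower. Surface and non-neural ectoderm genes were nearer to VN than on LN411E8 or LN511E8, with a median of -0.34 (percentile 0.67), 8 of 23 at least 2-fold lower and none higher, and GRHL3 at 7.59-fold lower. Eye field and retina genes had a median of 0.41 (percentile 99.2) with 6 of 14 at least 2-fold higher and 5 lower. The median turned to -0.40, within the random range (percentile 18.05), when dim genes entered with no filter. Neuroectoderm genes had a median of 0.34 (percentile 98.9), with FEZF1 5.67-fold and HESX1 3.35-fold higher, and of -0.12 with spike-in scaling. Laminin chain and basement membrane genes had a median of 0.49 (percentile 99.95), with HSPG2 2.53-fold and LAMA5 2.19-fold higher. Pluripotency genes had a median of -0.31 (percentile 0.03), with NODAL 7.37-fold lower. Integrins and YAP/TEAD targets both had medians of 0.01, at percentiles 52.1 and 42.4. Of 16542 genes compared, 986 were at least 2-fold higher and 1388 lower, or 41.5% higher. That share was 11.4% with spike-in scaling and 52.5% with normexp, which counted 508 and 459.

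On LN111E8, compared with VN, HAPLN1 was 45.4-fold lower, NPY 29.2-fold, TTC29 24.4-fold, the WNT modulator DACT1 16.6-fold, GRHL3 16.0-fold, BMPER 15.3-fold and WNT6 14.3-fold. The largest higher value was that of the ribosomal RNA gene RNA5-8SN5, at 9.62-fold. Others were those of NAPSA (9.13-fold), MEG3 (8.63-fold), RAX (7.13-fold), SIX3-AS1 (6.41-fold), FER1L4 (5.78-fold) and TXNIP (5.26-fold). EXD3 was 6.05-fold higher by its chosen probe and 0.93 log2 lower by its other probe. Of 23 Neural crest genes, 16 were at least 2-fold lower and none higher (median -1.69, percentile 0). PAX3 was not well above background there by its chosen probe, and 3.58 log2 lower by its other probe. Surface and non-neural ectoderm genes had a median of -0.86 (percentile 0), with MSX2 at least 7.98-fold lower.

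Neuroectoderm genes as a list did not leave the random range on LN111E8 (median -0.05, percentile 40.0, with 4 of 22 at least 2-fold higher and 4 lower): FEZF1 was 3.20-fold and LMO3 3.93-fold higher, whereas POU3F2 was 4.99-fold and FABP7 2.62-fold lower. Eye field and retina genes did not either (median -0.15, percentile 13.2), with SIX3 4.32-fold higher and PAX2 at least 31.6-fold lower. BMP/SMAD targets had a median of -0.60 (percentile 0), led by MSX1 at least 26.4-fold, the BMP antagonist genes NOG 11.4-fold and GREM1 9.20-fold, all lower. Without the targets that are also in lineage or WNT lists, the median was -0.05 (percentile 43.8) and the mean -0.76, with 4 of 14 at least 2-fold lower and none higher. Epithelial-mesenchymal transition genes had a median of -0.60 (percentile 0), with SNAI2 at least 19.3-fold and ZEB1 4.05-fold lower. Integrins had a median of -0.22 (percentile 2.16), with ITGA8 at least 3.60-fold and ITGA1 2.39-fold lower. Pluripotency genes (median 0.07, percentile 89.6) and YAP/TEAD targets (median -0.12, percentile 15.5) stayed within the range, although FOXD3 was 9.59-fold, NODAL 3.77-fold and GDF3 2.13-fold lower. Laminin chain and basement membrane genes had a median of 0.16 (percentile 98.8), with NID2 1.59-fold and LAMA1 1.46-fold higher. Of 16713 genes compared, 413 were at least 2-fold higher and 816 lower, against 171 and 350 with normexp. The higher genes made up 33.6%, and 22.3% with spike-in scaling.

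LN211E8 lay closest to VN. The largest lower values on LN211E8 were those of NNMT, nicotinamide N-methyltransferase (19.8-fold), ABCB9 (11.1-fold), NPPB (8.80-fold), HSPA12A (3.30-fold) and the metallothionein gene MT2A (2.91-fold). Among the largest higher values were those of MYOZ1 (4.26-fold), MBD5 (3.90-fold), RGS20 (3.84-fold), RNA5-8SN5 (3.61-fold) and RAX (3.06-fold). SIX3 was 2.35-fold and CRX, a photoreceptor factor, 2.27-fold higher, and 4 of 14 Eye field and retina genes were at least 2-fold higher with none lower (median 0.05, percentile 89.1).

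Neural crest genes were slightly lower on LN211E8 than on VN (median -0.11, percentile 1.12), with SNAI2 2.19-fold, TFAP2B 2.13-fold and NR2F1 2.05-fold lower and the other 21 of 24 within 2-fold. Surface and non-neural ectoderm genes stayed within the random range (median 0.06, percentile 95), with GATA3 2.04-fold higher. Preplacodal and lens genes had a median of 0.19 (percentile 99.7) and no member past 2-fold. Neuroectoderm genes lay at the edge of the random range, with a median of 0.08 (percentile 97.7, or 97.47 with another draw of random lists). The median was -0.0777 with spike-in scaling (percentile 97.3) and -0.00328 by the mean of all probes (percentile 59.98), both within the random range. Laminin chain and basement membrane genes had a median of 0.12 (percentile 99.8), and of -0.0149 with spike-in scaling. Pluripotency genes (median 0.04, percentile 94.0), Integrins (median -0.06, percentile 11.4) and YAP/TEAD targets (median -0.04, percentile 20.4) stayed within the range. Of 16949 genes compared, 107 were at least 2-fold higher and 248 lower, against 55 and 104 among genes above background on both arrays and 36 and 96 with normexp. Where a gene with at least 2-fold difference had a further probe, 55.6% of 9 such probes had the same sign, against 88.8% of 170 for LN511E8 and VN.

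**Figure D3:**
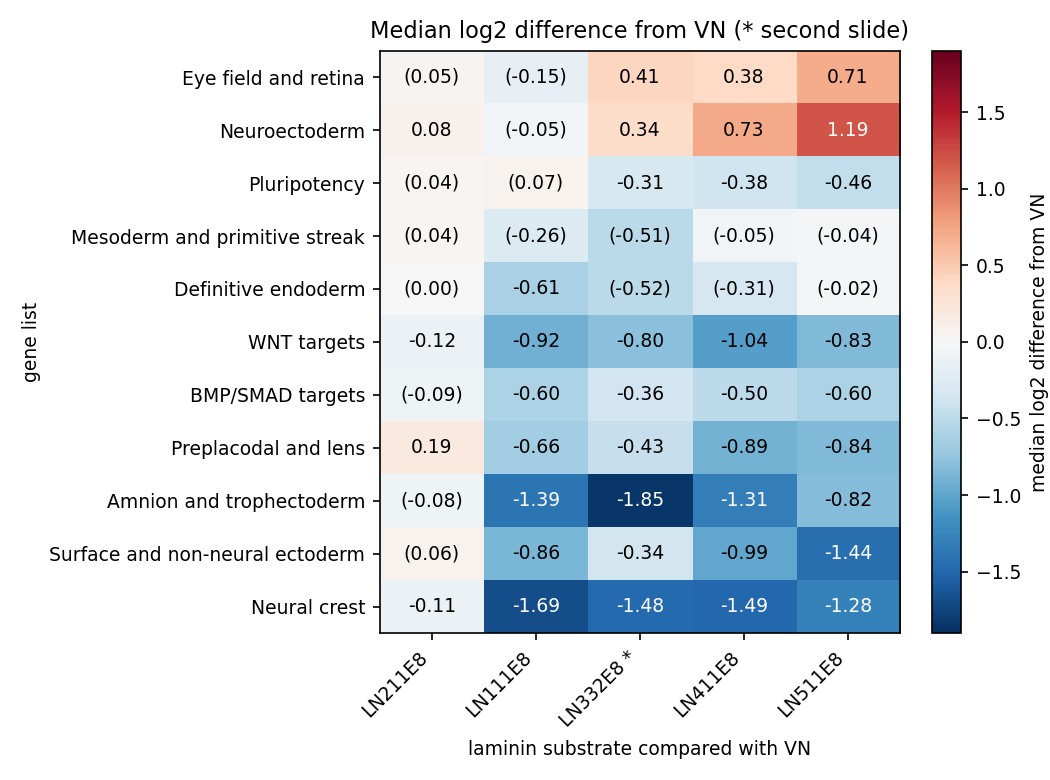
Median log2 difference from VN (colour and printed value) of 11 gene lists (vertical axis) on the 5 laminin substrates (horizontal axis), with medians inside the range of random lists in parentheses and an asterisk on LN332E8, the array of the second slide. The Neural crest medians were -0.11 on LN211E8 and -1.28 to -1.69 on the other 4 laminins, and the Neuroectoderm median was 1.19 on LN511E8.

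Without VN, LN211E8 and LN511E8 were set against each other on 1 slide. HAPLN1 was 272-fold higher on LN211E8, PAX7 24.9-fold (1.02 log2 by its other probe), GRHL3 24.4-fold, TFAP2A 19.9-fold, CABP7 18.8-fold, CYP1B1 15.8-fold and NPY 14.3-fold. LHX2 was 104-fold lower, RAX 49.2-fold, HES5 45.9-fold, SMOC1 17.7-fold, SIX3-AS1 15.4-fold, the chromatin remodeller gene CHD5 12.4-fold, the transition factor gene ZEB1 12.2-fold and LMO3 12.2-fold. The retinal gene SIX6 was at least 14.8-fold lower.

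Of 24 Neural crest genes, 14 were at least 2-fold higher on LN211E8 than on LN511E8 and 2 lower (median 1.05, percentile 100), and of 24 Surface and non-neural ectoderm genes 17 were higher and 1 lower (median 1.38, percentile 100). Of 22 Neuroectoderm genes, 14 were at least 2-fold lower and none higher (median -1.29, percentile 0), and Eye field and retina genes had a median of -0.51 (percentile 0) with 7 of 16 lower and 3 higher. Epithelial adhesion genes had a median of 0.66 (percentile 100), with CLDN4 3.37-fold and CDH1 2.38-fold higher on LN211E8. Pluripotency genes had a median of 0.45 (percentile 100), with NODAL 4.29-fold and PRDM14 2.05-fold higher. WNT targets had a median of 0.47 (percentile 100) and BMP/SMAD targets of 0.69 (percentile 100). Integrins (median 0.01, percentile 33.4), YAP/TEAD targets (median 0.10, percentile 80.0) and Laminin chain and basement membrane genes (median -0.03, percentile 11.46) stayed within the random range, with ITGA1 2.24-fold and LAMA4 2.43-fold higher and NID1 2.06-fold lower. Of 17020 genes compared, 490 were at least 2-fold higher and 666 lower on LN211E8, against 209 and 241 with normexp.

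LN332E8 was compared with LN511E8 across the 2 slides, so slide and substrate cannot be told apart here. Surface ectoderm genes were higher on LN332E8, and Preplacodal and lens genes stayed within the random range (median 0.04, percentile 45.4), with 3 of 16 at least 2-fold higher and 2 lower. GATA3-AS1 was 7.62-fold higher, GATA3 at least 3.53 log2, DLX5 4.32-fold, DLX6 4.21-fold and GRHL3 3.55-fold. The calcium pump gene ATP2C2 was 4.53-fold and the serine protease gene HPN 3.89-fold higher, and Epithelial adhesion genes had a median of 0.85 (percentile 100) with 6 of 25 at least 2-fold higher, CLDN4 at 3.11-fold and RAB25 at 2.52-fold. HES5 was 19.9-fold lower on LN332E8, the heparan sulfatase gene SULF1 12.4-fold, LMO3 11.4-fold, TBX1 11-fold, CHD5 10.4-fold, WNT5B 8.08-fold, ZEB1 8.02-fold and IGFBP3 7.71-fold.

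In this pair, 9 of 22 Neuroectoderm genes were at least 2-fold lower on LN332E8 and none higher (median -0.84, percentile 0), and 8 of 13 Eye field and retina genes were lower and 1 higher (median -1.93, percentile 0), with SIX6 8.0-fold, LHX2 6.29-fold and RAX 6.0-fold lower. Of 22 Surface and non-neural ectoderm genes, 9 were at least 2-fold higher and 1 lower (median 0.96, percentile 100). Neural crest genes stayed within the random range (median 0.25, percentile 93.1), with NR2F2 4.88-fold and NR2F1 4.57-fold lower, and PAX7 3.39-fold higher by its chosen probe, with another probe of the opposite sign. Pluripotency genes (median 0.11, percentile 20.8), Integrins (median 0.04, percentile 30.2), YAP/TEAD targets (median 0.28, percentile 95.8) and Laminin chain and basement membrane genes (median 0.16, percentile 59.9) did not leave the range. Of 16450 genes compared, 321 were at least 2-fold higher and 925 lower on LN332E8, or 25.8% higher, against 120 and 225 with normexp. The share higher was 6.36% with spike-in scaling and 38.2% with quantile normalization.

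LN211E8 and LN332E8, also on different slides, were compared last. On LN211E8, HAPLN1 was 65.2-fold higher, AFP 22.4-fold, TTC29 17.1-fold, the chemokine gene CXCL14 15.2-fold and EPAS1 14.8-fold. LHX2 was 16.5-fold lower, MEG3 14.6-fold, the vault protein gene MVP 10.1-fold, RAX 8.21-fold, TXNIP 7.74-fold and the metallothionein gene MT1X 6.31-fold. Of 24 Neural crest genes, 12 were at least 2-fold higher on LN211E8 and none lower (median 0.91, percentile 100), with TFAP2B at least 14.6-fold and FOXD3 14.1-fold higher. Surface and non-neural ectoderm genes had a median of 0.48 (percentile 99.99) and Eye field and retina genes of -0.87 (percentile 0) but a mean of -0.12, with 5 of 15 at least 2-fold higher and 4 lower, while Neuroectoderm genes (median -0.14, percentile 24.6) stayed within the range. Pluripotency genes had a median of 0.27 (percentile 99.98), with NODAL 3.53 log2 higher, and Laminin chain and basement membrane genes a median of -0.34 (percentile 0.61), with LAMA5 1.9-fold lower. Integrins (median -0.02, percentile 52.6) and YAP/TEAD targets (median 0.02, percentile 72.2) stayed within the range. Of 17103 genes compared, 1114 were at least 2-fold higher and 732 lower on LN211E8, or 60.4% higher, against 276 and 277 with normexp. The share higher was 84.8% with spike-in scaling and 49.0% with quantile normalization.

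Genes at least 2-fold above every other substrate numbered 194 on LN511E8, 136 on VN, 52 on LN211E8, 48 on LN111E8, 46 on LN411E8 and 6 on LN332E8. On LN511E8 the largest gaps among genes detected on all arrays were those of HES5 (7.58-fold above the next substrate), KLHDC8A (4.91-fold), NPY2R (4.43-fold), ZEB1 (4.25-fold) and PRSS23 (3.56-fold). On VN they were those of NPPB (7.52-fold), NNMT (6.29-fold), TKTL1 (2.47-fold) and MUSTN1 (2.11-fold). On LN211E8 they included those of RBL1 (2.28-fold), RGS20 (2.27-fold), NR4A3 (2.17-fold) and MBD5 (2.12-fold). NAPSA (5.23-fold), DTX3 (2.5-fold) and TMEM221 (2.16-fold) led on LN111E8, KLRA1P (5.91-fold), SUN2 (4.26-fold) and DDX11-AS1 (3.44-fold) on LN411E8, and KLK8 (2.16-fold) on LN332E8, the array of the second slide. Most of these genes were not detected on all arrays: with only genes detected on all arrays compared, the counts were 54, 24, 7, 6, 3 and 1 in the same order. In the other genes the gap can be a bound, and how many such gaps were bounds was not counted. Further probes of these genes were highest on the same array in 15.8% of 19 cases for LN111E8, LN211E8 and LN411E8, in 62.1% of 29 for LN511E8 and in 25% of 16 for VN.

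Genes at least 2-fold below every other substrate numbered 170 on LN332E8, where slide and substrate cannot be told apart, and 21 on LN111E8, 20 on LN411E8, 20 on VN, 9 on LN511E8 and 3 on LN211E8. These counts moved with the processing: the 170 became 20 with normexp. Without the LN332E8 array the counts were 38 on LN111E8 and 80 on LN411E8, but leaving out an array can only keep or raise such counts. On VN the largest such gaps were those of RNA5-8SN5 (3.61-fold), RAX (3.06-fold), SIX3-AS1 (2.66-fold), the complement gene C3 (2.45-fold) and SIX3 (2.35-fold). On LN111E8 they were those of the collagen gene COL2A1 (4.44-fold), MEN1 (3.92-fold), NOG (3.55-fold), DACH1 (3.43-fold) and ZNF503 (2.95-fold). On LN511E8 they were those of BNIPL (2.80-fold), GATA3-AS1 (2.73-fold), ATP2C2 (2.37-fold), BIK (2.02-fold) and CLDN4 (2.02-fold). DIABLO (7.18-fold), NPPB (4.69-fold) and CBL (3.11-fold) led on LN411E8, and APOOP5 (7.26-fold), FAM177B (3.52-fold) and YY2 (3.34-fold) on LN332E8.

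The ribosomal RNA gene RNA5-8SN5 was lowest on VN. Against VN it was 9.62-fold higher on LN111E8, 3.61-fold on LN211E8, 14.2-fold on LN332E8 (second slide) and 10.3-fold on LN411E8, and on LN511E8 it was 3.24 log2 higher. The 7 spike-in probes of known input, taken relative to each array's 75th percentile and then to their mean over arrays, lay at 0.28 on LN332E8, -0.19 on VN and -0.05 to 0.02 on the other 4 arrays. These values thus also hold differences in the 75th percentile, which was lowest on LN332E8. Scaling to them in place of the 75th percentile moved the median difference of all genes from VN by -0.16 on LN111E8, -0.16 on LN211E8, -0.47 on LN332E8, -0.20 on LN411E8 and -0.13 on LN511E8. It moved the median by -0.33 for LN332E8 against LN511E8 and 0.31 for LN211E8 against LN332E8, and the deposited value table moved it by -0.11 for LN332E8 against LN511E8.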

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

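The tests on WNT targets, BMP targets and further probes were chosen, or put in their final form, after the result was seen. Probes whose accession matched no single gene form data outside the comparisons above, and they too held signal above the VN array: 367 such probes were at least 2-fold above VN on LN111E8, 153 on LN211E8, 566 on LN332E8 (second slide), 575 on LN411E8 and 526 on LN511E8. Those at least 2-fold below VN numbered 577, 451, 1522, 794 and 454 in the same order, among 9494, 9836, 8907, 9274 and 7968 compared.

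The pattern a biologist would look at first is that the median of eye field genes was highest on LN511E8, whereas those of neural crest and surface ectoderm genes were highest on VN and LN211E8. VN and LN511E8 shared a slide column and still differed, with a Neuroectoderm median of 1.19. LN211E8 and VN, the closest pair of arrays (SD 0.26), shared a slide row, as did LN111E8 and LN511E8 (SD 0.41). An effect of the position on the slide was not tested, and for LN211E8 and VN it cannot be told apart from a likeness of the substrates. A slower exit from pluripotency was not tested: Pluripotency genes had a median 0.45 log2 higher on LN211E8 than on LN511E8 (percentile 100), but on LN111E8 against VN they stayed within the random range (median 0.07, mean -0.11, 3 of 24 at least 2-fold lower and none higher), where Neural crest genes had a median of -1.69 and Surface and non-neural ectoderm genes of -0.86. WNT targets that belong to no lineage or BMP list had a median 0.38 log2 higher on LN211E8 than on LN511E8 (percentile 99.99), with RNF43 1.65, SP5 1.5 and AXIN2 1.23 higher and DKK1 at -1.05. The same WNT targets had a median of -0.92 on LN111E8 against VN, yet the Neuroectoderm and Eye field and retina medians there stayed within the random range (percentiles 40.0 and 13.2). Members of both lists went both ways there: 4 of 22 Neuroectoderm genes were at least 2-fold higher and 4 lower, and 3 of 13 Eye field and retina genes higher and 5 lower. BMP targets that belong to no lineage or WNT list had a median 0.40 log2 higher on LN211E8 than on LN511E8 (percentile 99.99), but their median of -0.27 on LN511E8 against VN stayed within the random range (percentile 3.4), as did that of -0.05 on LN111E8 (percentile 43.8). Their means were lower, at -0.64 on LN511E8 and -0.76 on LN111E8, with 4 of 14 targets at least 2-fold lower and none higher in each pair. Effects of WNT and of BMP signalling cannot be told apart here. The LN111E8 medians decide for or against neither, since members of these lists moved by at least 2-fold while the medians stayed within the random range. A difference between single cultures, or in the share of cell types, stays open as well.

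A further pattern is the number of genes at least 2-fold above every other substrate. For LN111E8, LN211E8 and LN411E8, further probes of the same genes were highest on the same array in 15.8% of 19 cases (exact 95% interval 3.38 to 39.6%), where 1 array in 6 is expected by chance. None of the 19 was detected on all arrays, so artefacts of single spots cannot be told apart from differences that these probes were too dim to follow. The share was 62.1% of 29 for LN511E8 (42.3 to 79.3%) and 25% of 16 for VN (7.27 to 52.4%), of which 9 and 4 were detected on all arrays, and this leaves open how many of their 194 and 136 genes come from single spots. With dim signals set to each array's floor, the shares were 10.5% for the first 3 arrays, 55.2% for LN511E8 and 43.8% for VN.

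The last pattern is the 170 genes at least 2-fold below every other substrate on LN332E8, the array of the second slide. These genes were dim, with a median level of -1.65 on the other arrays, against 1.35 for all genes detected on those 5. A shift of all dim genes by a trend of the slide with intensity is argued against as the whole cause, since the other 3041 genes in the same range of levels had a median gap of -0.00766 log2. The median gap of -1.47 for the 170 follows from how they were chosen. A weaker trend was present, with a median gap of -0.17 in the lowest decile of levels and 0.15 in the highest. A wider scatter of dim probes on this array was not tested. Hybridization of single probes on the second slide cannot be told apart from an effect of the substrate, because 40% of only 15 further probes were also lowest on LN332E8 (exact 95% interval 16.3 to 67.7%), or 46.7% (21.3 to 73.4%) with dim signals at the floor. The count was 93 with quantile normalization, 20 with normexp and 408 with spike-in scaling, and part of it may go with intensity, since quantile normalization removes such a trend.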

How the results depend on the processing

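Of the settings below, leaving out the LN332E8 array was chosen after seeing the data. Of the 150 list medians outside the random range, 132 kept their side with normexp, 142 with quantile normalization, 150 with median scaling, 149 with spike-in scaling, 150 with the deposited value table, 142 of 149 with genes detected on both arrays, 137 with no filter and 142 with the mean of probes, and none crossed to the opposite side. Median scaling, spike-in scaling and the deposited value table shift all values of an array alike. A list then moves with its random lists and its percentile can hardly change, so the counts for these settings are no check. Of 513 named differences past 2-fold, 377 stayed past it with normexp, 475 with spike-in scaling and 491 with quantile normalization, and none changed sign. These differences were picked for their size. Spike-in scaling moved no pair by more than 0.47 log2, and so could not turn the sign of a difference past 2-fold. Settings that treat dim probes otherwise moved many of the counts by over 1.5 times. Spike-in scaling did so for LN332E8 and for genes below every other substrate on LN411E8 and VN. Quantile normalization did so for genes above or below every other substrate on LN332E8. Why the counts moved with these settings was not tested.

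With normexp, which compresses dim signals by its offset, genes at least 2-fold higher and lower than on VN numbered 171 and 350 on LN111E8, 36 and 96 on LN211E8, 508 and 459 on LN332E8, 395 and 481 on LN411E8, and 279 and 308 on LN511E8. They were 209 and 241 for LN211E8 against LN511E8, 120 and 225 for LN332E8 against LN511E8, and 276 and 277 for LN211E8 against LN332E8. Genes above and below every other substrate were 17 and 7 on LN111E8, 21 and 1 on LN211E8, 1 and 20 on LN332E8, 21 and 8 on LN411E8, 75 and 3 on LN511E8, and 62 and 4 on VN. The SD of log2 differences from LN111E8 was 0.301 for LN211E8, 0.314 for LN332E8, 0.271 for LN411E8, 0.322 for LN511E8 and 0.391 for VN. From LN211E8 it was 0.446 for LN332E8, 0.423 for LN411E8, 0.382 for LN511E8 and 0.197 for VN. From LN332E8 it was 0.263 for LN411E8, 0.381 for LN511E8 and 0.530 for VN. It was 0.274 between LN411E8 and LN511E8, 0.504 between LN411E8 and VN, and 0.428 between LN511E8 and VN.

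With no filter and no bound, more dim genes entered. Genes higher and lower than on VN were 930 and 1430 on LN111E8, 480 and 2686 on LN211E8, 1582 and 2411 on LN332E8, 1457 and 1783 on LN411E8, and 1253 and 1204 on LN511E8. They were 980 and 1733 for LN211E8 against LN511E8, 748 and 1751 for LN332E8 against LN511E8, and 1878 and 1410 for LN211E8 against LN332E8. Above and below every other substrate were 108 and 55 on LN111E8, 116 and 46 on LN211E8, 71 and 336 on LN332E8, 145 and 66 on LN411E8, 351 and 44 on LN511E8, and 319 and 110 on VN. The Eye field and retina median of LN332E8 against VN turned from 0.41 to -0.40, within the random range (percentile 18.05).

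With genes detected on both arrays only, 541 were lower on LN111E8 than on VN, and 55 higher and 104 lower on LN211E8. Above every other substrate were 6 on LN111E8, 7 on LN211E8, 1 on LN332E8, 3 on LN411E8, 54 on LN511E8 and 24 on VN, and 1 was below on LN211E8.

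With spike-in scaling, 393 genes were higher and 3046 lower on LN332E8 than on VN, 109 and 1605 than on LN511E8, and LN211E8 had 2041 higher and 366 lower than LN332E8. On LN332E8, 3 genes were above and 408 below every other substrate, and 12 were below on LN411E8 and 11 on VN. Medians against VN turned to -0.0591, -0.0349 and -0.0261 for Ribosomal proteins on LN111E8, LN332E8 and LN411E8, to -0.0777 and -0.123 for Neuroectoderm on LN211E8 and LN332E8, to -0.0149 and -0.0356 for Laminin chains and basement membrane and Epithelial adhesion on LN211E8, and to -0.0153 for p53 targets on LN332E8. This scaling shifts all genes of a pair alike, so the turn of a small median is part of that shift: it was -0.16 for LN111E8, -0.20 for LN411E8 and -0.47 for LN332E8. The percentiles of Ribosomal proteins under it were 99.7 on LN111E8, 99.86 on LN411E8 and 100 on LN332E8, and that of p53 targets on LN332E8 was 99.84. Such a shift moves a list and its random lists alike, so these percentiles are no separate check. With quantile normalization, 11 genes were above and 93 below every other substrate on LN332E8. Without the LN332E8 array, 38 were below every other substrate on LN111E8 and 80 on LN411E8, and leaving out an array can only keep or raise such counts. With the mean of probes, the Neuroectoderm median of LN211E8 against VN was -0.00328, within the random range (percentile 59.98).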

Other observations

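Other gene groups differed between the substrates as well. Hypoxia and glycolysis genes were higher than on VN on LN111E8 (median 0.44, percentile 100), LN211E8 (0.21, percentile 100), LN411E8 (0.55, percentile 100) and LN511E8 (0.34, percentile 99.99), and within the random range on LN332E8 (0.22, percentile 89.8, second slide). All of these comparisons share the VN array, on which 12 of 24 members were lowest, so they are not independent. BNIP3, a mitophagy receptor gene, was 2.84-fold higher on LN111E8 and 2.97-fold on LN411E8, PDK1 2.33-fold on LN111E8 and 2.27-fold on LN511E8, and ANKRD37 3.50-fold on LN511E8. With spike-in scaling the median of all genes moved by -0.13 to -0.20 in the 4 pairs outside the range, and these list medians kept their sign. Unfolded protein and amino acid stress genes had medians against VN of -0.31 on LN111E8, -0.30 on LN211E8, -0.19 on LN332E8 (second slide), -0.46 on LN411E8 and -0.66 on LN511E8. These 5 comparisons share the VN array, on which 17 of 25 members were highest, so they are not independent. SLC7A11, the cystine transporter gene, was 3.74-fold lower on LN111E8, 5.13-fold on LN411E8 and 4.47-fold on LN511E8, and NUPR1 4.94-fold on LN511E8. Actin and contractility genes had medians against VN from -0.15 on LN211E8 to -0.54 on LN111E8, with 13 of 22 members highest on the shared VN array. CNN1, a calponin gene, was 3.69-fold lower on LN411E8 and 3.03-fold on LN511E8.

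Cholesterol and fatty acid synthesis genes were lower than on VN on LN111E8 (median -0.30), LN332E8 (-0.26, second slide), LN411E8 (-0.44) and LN511E8 (-0.44), but not on LN211E8 (0.02, percentile 89.2). STARD4, a sterol carrier gene, was 2.79-fold lower on LN411E8 and 1.83-fold on LN511E8. Genes of the list p53 targets and apoptosis were higher on LN411E8 (median 0.22) and LN511E8 (0.19), with BTG2 3.74-fold and 3.55-fold higher and 5 of 25 and 2 of 24 members at least 2-fold higher. With spike-in scaling, which shifted all genes of these pairs by -0.20 and -0.13, the medians were 0.0165 and 0.0546. On LN332E8 their median was 0.36, with GDF15 3.26-fold higher, which holds the slide difference. It was -0.0153 with spike-in scaling, which shifted all genes of that pair by -0.47, and the list's percentile under it, which such a shift can hardly change, was 99.84. TXNIP had levels of 1.86 on VN, 2.65 on LN211E8, 4.25 on LN111E8, 5.34 on LN511E8, 5.6 on LN332E8 and 5.82 on LN411E8. Cell cycle genes stayed within the random range against VN on 4 laminins and had a median of -0.23 on LN411E8 (percentile 1.14), where RRM2 was 2.24-fold lower. Ribosomal protein genes had medians of 0.10 on LN111E8, 0.18 on LN411E8 and 0.43 on LN332E8 (second slide) against VN. With spike-in scaling, which shifted all genes of these pairs by -0.16, -0.20 and -0.47, they were -0.0591, -0.0261 and -0.0349, at percentiles 99.7, 99.86 and 100, which such a shift can hardly change. On LN511E8 the median was 0.16 (percentile 100), and 0.0319 with spike-in scaling.

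Genes of lineages outside the ectoderm were near VN or lower. Mesoderm and primitive streak genes stayed within the random range against VN on all 5 laminins, and Definitive endoderm genes on 4, with a median of -0.61 on LN111E8 (percentile 0.3). Single members still differed: 4 of 11 Mesoderm and primitive streak genes were at least 2-fold lower on LN511E8 and none higher (mean -0.60). On LN411E8, 4 of 12 were lower and 1 higher (mean -0.65), and on LN211E8 none passed 2-fold. AFP, a member of the Definitive endoderm list, was 6.51-fold lower on LN111E8, 33.2-fold on LN332E8 (second slide) and 42.7-fold on LN411E8. Amnion and trophectoderm genes, a list that shares TFAP2A, WNT6, HAND1 and GATA3 with the surface ectoderm list, had medians of -1.39 on LN111E8, -1.85 on LN332E8, -1.31 on LN411E8 and -0.82 on LN511E8, against -0.08 on LN211E8 (percentile 7.06). HAPLN1 had the largest difference named in the LN511E8 and VN pair, 260-fold, and was in none of the lists fixed beforehand.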
